A study of Mus musculus with 6 samples.

How the data were processed

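The 6 arrays of newborn mouse ovary were 2 wildtype and 4 double knockout for Sohlh1 and Sohlh2, with a mixed C57BL/6/129S6/SvEv background per the labels. Total RNA was extracted with an RNeasy kit and DNase, amplified and biotin-labelled with the Illumina TotalPrep kit, and hybridised to Illumina MouseWG-6 BeadChips, per the labels' protocols. Signals were processed with GenomeStudio, per the submitters' processing notes, which give no version. All 6 arrays lay on 1 slide. Titles and descriptions number the samples differently, and the numbers of the titles are used here (wildtype 2 and 3, double knockout 1, 2, 3 and 5).

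The raw table deposited by the authors gives a signal intensity per probe and array, without background subtraction or normalization as the values show (array medians 59.3 to 61.1, upper quartiles 131.6 to 165.8). The detection column deposited beside each signal is a score equal to 1 minus the detection p, as its relation to the signal shows, and it was turned into a p. The series matrix deposited by the authors holds intensity values on a linear scale. Set against the raw signals, they run in the same direction, are quantile normalized, and are neither background-subtracted nor centred. Their column medians were 59.6 for double-knockout array 1 and 59.5 for each of the other arrays. Each column matched its own array's raw signals by rank at 0.99999 and other arrays at no more than 0.919.

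The background was corrected with normexp from the detection p-values (nec in limma 3.58.1, R 4.3.3), an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale. A probe was tested where its detection p was under 0.05 on at least 2 of the 6 arrays, which kept 21981 of 45281 probes. Genotypes were compared with limma's lmFit and eBayes on all 6 arrays with no covariate, and adjusted by Benjamini-Hochberg at 0.05. At this threshold 796 probes were lower and 802 higher in the double knockout, 1598 in all, and 5383 had an unadjusted p under 0.05. Probes were named from the platform annotation: 34885 had 1 gene symbol, 18 several and 10378 are unnamed here. The Entrez numbers of 34807 probes matched the GRCm38.p6 gene table, which updated 0 symbols and otherwise served only for gene order. Each gene was represented by its tested probe with the highest mean over all arrays, which gave 12163 genes from 18695 probes; 3286 tested probes had no single gene. Of 338 called genes with more than 1 tested probe, 49 had a probe of opposite sign and 0 had called probes in opposite directions. Where a probe was not detected on any array of the dimmer group, the fold is a bound against the lowest detected signal of those arrays or the probe's own signal, whichever was higher, and is written as at least that fold.

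Named genes followed a rule written before the data were examined. It took the targeted genes and the 12 largest falls and 12 largest rises among called genes with all arrays apart and detected in the brighter group, leaving out clone-named genes. From each list it took up to 4 called members with the largest change, or the 2 brightest where none passed, and further members of the oocyte, meiotic and germ cell lists, up to 12. Genes outside the rule are said to have been named after their values were seen.

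The 26 gene lists fixed before the data were examined were targeted genes, oocyte transcription factors, zona pellucida and oocyte-secreted factors, maternal effect and oocyte-stored genes, meiotic prophase, germ cell identity, piRNA pathway and transposon control, primordial germ cell and pluripotency genes, and markers of pregranulosa and granulosa, Sertoli and testis-determining, theca, steroidogenic and stromal, ovarian surface epithelium, endothelial, erythroid, macrophage and leukocyte, smooth muscle and pericyte, oviduct and mesonephric epithelium, and adipocyte cells, with p53 targets and apoptosis, primordial follicle activation, Notch pathway, proliferation, immediate early and heat shock, reference, sex-linked and extracellular matrix genes. The 23 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Lists of mast cell, interferon-stimulated, Magea and Rhox genes were chosen after seeing the data.

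The procedure was tested on simulated data with 200 of 12163 genes changed, 50 at each size. It called 26% of genes changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 0 in the wrong direction. Unchanged genes made up 4.85% of calls. A simulated list of 20 genes shifted by 1 on the log2 scale was detected, and 0 of 200 unchanged lists had a camera p under 0.05. Simulated genes varied independently of each other, while estimated correlations within the tested lists ran from -0.046 to 0.74. The simulation therefore does not show how often lists of correlated genes are called falsely.

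Alternatives were no background correction, scaling to the 75th percentile, cyclic loess, an offset of 50, no filter, a stricter filter (detection p under 0.01 on all arrays of a group), a trended robust variance prior, array weights, the authors' normalized values, each array left out, the replicate number as a block, a threshold of 0.01, a minimum log2 change of 1, the mean of a gene's probes, and the other set tests.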

Results

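Total RNA from newborn mouse ovary was measured on Illumina MouseWG-6 BeadChips, with 2 arrays from wildtype animals and 4 from animals lacking both Sohlh1 and Sohlh2, which encode basic helix-loop-helix transcription factors of the germ line. Each array carried 45281 probes. Wildtype arrays 2 and 3 detected 20459 and 20594 of them, and double-knockout arrays 1, 2, 3 and 5 detected 20157, 20124, 20160 and 20331. The number of arrays limits the precision of every value. The labels do not say whether the samples were separate animals or litters, so the p-values measure only the spread between these samples. The wildtype arrays correlated at r = 0.990 across tested probes, the double-knockout arrays at 0.980 to 0.990 and arrays of different genotype at 0.969 to 0.980 (values across probes, which are not independent replicates). The first principal component held 49.4% of the variance and set the genotypes apart, and the second held 19.3% and set double-knockout array 3 (-34.5) against array 5 (32.0).

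The comparison asked which transcripts differ between the double-knockout and the wildtype newborn ovary. Sohlh1 itself was 9.82-fold lower in the double knockout, with a log2 level of 9.65 ± 0.18 (SD, n = 4) against 12.94 ± 0.09 (SD, n = 2). Its 2 probes gave log2 fold changes of -3.30 and -3.33 (double knockout over wildtype, as for all values given by gene), and both were still detected on all 4 double-knockout arrays. The single Sohlh2 probe was detected on 1 wildtype array and on 0 double-knockout arrays, and was not tested. Where these probes lie relative to the deleted parts is not known here, and a probe outside the deleted part checks nothing.

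Several transcripts known from oocytes were much lower in the double knockout. Ccno, a cyclin family member, was 21.6-fold lower (log2 fold change -4.43 ± 0.33 SE, n = 2 and 4). Lhx8, a LIM-homeobox transcription factor of oocytes, was 13.3-fold lower (-3.73 ± 0.14 SE, adjusted p = 1.2e-05). Gdf9, a growth factor secreted by oocytes, was 6.64-fold lower (-2.73 ± 0.32 SE), and Kit, the receptor for stem cell factor, was 4.96-fold lower (-2.31 ± 0.22 SE). In the other direction Sis, which encodes the gut enzyme sucrase-isomaltase, was 15.7-fold higher (3.97 ± 0.36 SE), and Rec8, a cohesin subunit of meiosis, was 4.56-fold higher (2.19 ± 0.24 SE). Sis was detected on 1 of 2 wildtype arrays, and its change was 4.72 without wildtype array 2 and 3.18 without wildtype array 3.

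Among 12163 genes tested, 437 were lower and 583 higher in the double knockout, 1020 or 8.39% in all. Of these, 210 were at least 2-fold lower and 238 at least 2-fold higher, and 44 and 28 passed 4-fold. The median over all tested genes was 0.03 on the log2 scale. The count was 160 without wildtype array 2, 289 without wildtype array 3 and 567 without double-knockout array 1. An exact permutation test of 2 arrays against 4 cannot give a two-sided p under 0.0667, so each call rests on the spread that limma pools across genes.

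The other large falls covered several functions. Noct, a circadian-regulated phosphatase, fell (-4.21 ± 0.20 SE), as did Syt16, of the synaptotagmin family (-4.09 ± 0.25), and Fbxw27, an F-box protein (-3.08 ± 0.22). Th, tyrosine hydroxylase, was not detected on any double-knockout array and was at least 7.27-fold lower after background correction, a bound that does not hold without it (-2.01). Slc27a2, a fatty acid transport protein (-2.95 ± 0.27), and Gpr143, a receptor of pigment cells (-2.73 ± 0.18), fell too. So did Nlrp14, of the NLR family in oocytes (-3.22 ± 0.53), Zp3, a zona pellucida glycoprotein (-2.73 ± 0.53), and Ap3b2, an adaptor protein subunit (-2.74 ± 0.50). Calls for these last genes ended without wildtype array 2 (adjusted p = 0.120 for Nlrp14, 0.181 for Zp3 and 0.15 for Ap3b2) and without wildtype array 3 (0.0554, 0.0846 and 0.0840). Noct was detected on 1, Fbxw27 on 2 and Syt16 on 3 of the 4 double-knockout arrays, so their changes are against background in part. With no background correction Noct gave -3.01, Syt16 -3.09, Lhx8 -3.05, Fbxw27 -2.06 and Slc27a2 -2.18, and the mean of a gene's probes gave -2.20 for Noct and -1.65 for Ap3b2, with every call kept. Another Noct probe gave -0.18 and another Ap3b2 probe -0.02, and Noct and Sis lie among the 100 tested genes nearest Sohlh2.

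Among the other large rises, Prss50, a serine protease of testis, rose by 3.12 ± 0.23 (SE), 8.67-fold, and Dpep3, a membrane dipeptidase of testis, by 2.66 ± 0.28. Tex19.2, of the Tex19 family in the germ line, rose by 2.60 ± 0.21, 6.07-fold. Xpnpep2, an aminopeptidase, rose by 2.91 ± 0.28, Cela2a, a pancreatic elastase, by 2.55 ± 0.15 and Krt84, a hair and nail keratin, by 2.77 ± 0.20. Svopl, a transporter-like protein, rose by 2.93 ± 0.23, Abca14, an ABC transporter, by 2.97 ± 0.26 and Cldn16, a tight junction claudin, by 2.57 ± 0.15. Rhox9 rose by 2.51 ± 0.20, and Rhox6, not detected on any wildtype array, was at least 4.33-fold higher after background correction, a bound that does not hold without it (1.51) or with an offset of 50 (1.44). Both are X-linked homeobox genes with near-identical relatives, which probes may not tell apart. Abca14 was detected on 1 of 2 wildtype arrays. With no background correction the changes were 3.05 for Sis, 2.44 for Prss50, 1.97 for Abca14, 2.09 for Svopl, 1.92 for Krt84, 1.70 for Cldn16, 1.71 for Cela2a and 1.91 for Rhox9, and the mean of a gene's probes gave 1.19 for Abca14, 2.23 for Svopl and 1.95 for Xpnpep2, with every call kept. The other Abca14 probes gave 0.28 and 0.33, and the other probes of Svopl and Xpnpep2 gave 1.54 and 0.98.

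**Figure D1:**
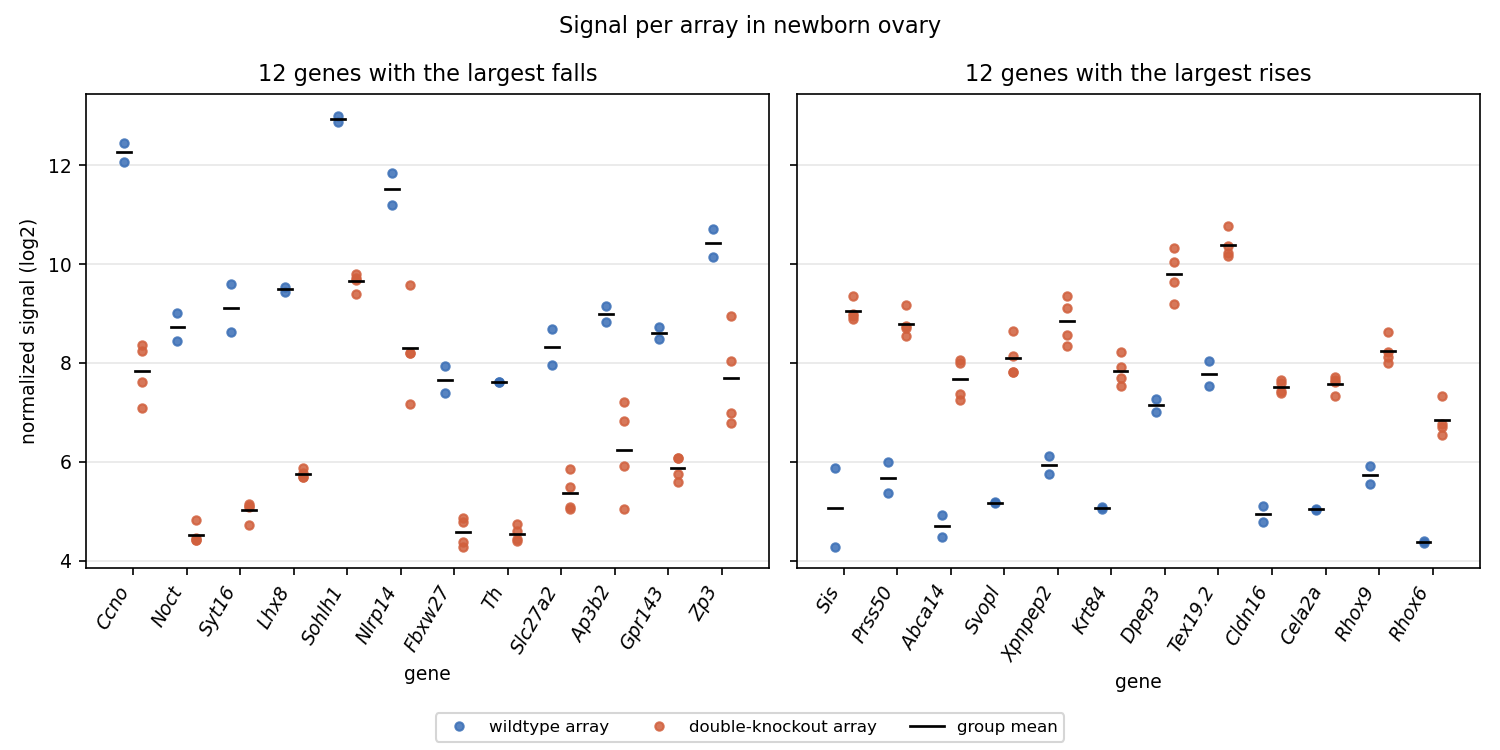
Normalized log2 signal on each array for the 12 genes with the largest falls and the 12 with the largest rises, with wildtype arrays (n = 2) in blue, double-knockout arrays (n = 4) in orange and black bars at group means. Each double-knockout array lies on one side of both wildtype arrays for every gene drawn, as the choice of genes required, and Sohlh1 keeps a level of 9.65 in the double knockout.

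Of 8 tested members of the oocyte transcription factor list, 7 fell, 0 rose and 1 did not pass. The list median was -1.26, with a camera adjusted p = 9.89e-10, or adjusted p = 0.447 with an estimated correlation. Adjusted over the list alone, 7 fell, and 4 did over all genes without wildtype array 2. That fit tested 7 of the 8 members. Besides Lhx8, the pluripotency factor Pou5f1 (-2.07), Foxr1 (-1.82) and Foxo3, which restrains growth of resting oocytes (-1.42), fell. So did Lin28a, an RNA-binding protein that was not detected on any double-knockout array (at least 1.39-fold lower, adjusted p = 0.049). This bound does not hold under every alternative (smallest change -0.33), and Lin28a kept its call under 7 of 16. Figla, which switches on zona genes, also fell (-1.09) and lost its call without either wildtype array (adjusted p = 0.0816 without 2 and 0.0605 without 3). Foxr1 was detected on 1 double-knockout array, and with no background correction it gave -1.08 and Pou5f1 -1.42. Nobox, another oocyte homeobox gene, gave -0.40 with adjusted p = 0.234.

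In the zona pellucida and oocyte-secreted factor list, which also holds the receptor Kit, 4 of 7 tested members fell (Zp3, Gdf9, Kit and Zp1). Of the others, 0 rose and 3 did not pass. The list median was -2.29, with a camera adjusted p = 3.29e-04, or adjusted p = 0.538 with an estimated correlation. Adjusted over the list alone, 5 fell. The number that fell was 2 without wildtype array 2 and without wildtype array 3, and with no filter it was 2 of these 7 and 3 of the 11 members then tested. Zp1, a zona glycoprotein, fell (-2.29) but lost its call without either wildtype array or double-knockout array 1, 2 or 3 (adjusted p up to 0.286), while Bmp15, a growth factor of oocytes, gave -0.06 (adjusted p = 0.918). Among 28 maternal effect and oocyte-stored genes, 12 fell, 1 rose and 15 did not pass (median -1.09; camera adjusted p = 4.88e-09; adjusted p = 0.538 with an estimated correlation). When adjusted over the list alone, 15 fell and 1 rose. The number that fell was 4 without wildtype array 2, 6 without wildtype array 3 and 5 with no filter, which tested 43 members. Uchl1, a deubiquitinase (-2.71), Npm2, an oocyte nucleoplasmin (-2.54), Btg4, which acts in maternal mRNA clearance (-2.23), and Mos, a kinase of meiotic arrest (-2.08), fell. Npm2 was detected on 2 and Mos on 1 of the double-knockout arrays, and with no background correction they gave -1.66 and -1.23. The member that rose was Nlrp4c (0.88), named after its value was seen, which kept its call only without double-knockout array 2 among the left-out arrays (adjusted p up to 0.237).

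Meiotic genes moved both ways: of 24 tested members of the meiotic prophase list, 4 fell, 3 rose and 17 did not pass. The list had a median of -0.03 and a mean of 0.01, with a camera test that pointed down (adjusted p = 0.735). The counts adjusted over the list alone were 5 that fell and 4 that rose. Over all genes, 0 fell and 2 rose without wildtype array 2, and without wildtype array 3, 2 fell and 1 rose. Besides Rec8, Sycp2, a synaptonemal complex component, rose by 1.00 and Mnd1, a recombination factor, by 0.90. Tex11, a recombination gene on the X chromosome, fell (-1.49), as did Smc1b, a meiotic cohesin subunit (-1.36). Without wildtype array 2, adjusted p was 0.0509 for Tex11, 0.0917 for Smc1b and 0.315 for Sycp2, and without wildtype array 3 it was 0.0979 for Mnd1 and 0.0934 for Sycp2. Sycp2 also lost its call without double-knockout arrays 1, 3 and 5 (0.0769, 0.0622 and 0.0643).

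Of 24 tested germ cell identity genes, 8 fell, 6 rose and 10 did not pass (median -0.45; camera adjusted p = 0.0431; adjusted p = 0.662 with an estimated correlation). When adjusted over the list alone, 11 fell and 7 rose. The list includes Sohlh1, a targeted gene whose fall the genotype could set in advance. Its counts and camera test were not repeated without Sohlh1. Over all genes, 2 fell and 3 rose without wildtype array 2, without wildtype array 3, 4 fell and 4 rose, and without double-knockout array 1, 5 fell and 6 rose. Sohlh1 and Kit fell while Rhox9, Rhox6 and Rhox13 (1.69) rose, as did Dnd1 (1.29), an RNA-binding protein of germ cells, which lost its call without wildtype array 2 (adjusted p = 0.0996) or 3 (0.0902). Ddx4, the germ cell RNA helicase, gave -0.40 (adjusted p = 0.278) and Dazl, a germ cell RNA-binding protein named after its value was seen, gave -0.27 (adjusted p = 0.491). The Ddx4 probe was dim, with log2 levels of 5.76 in wildtype and 5.36 in double-knockout arrays. The lowest detected signals of the arrays were 4.72 to 4.76, so background may compress a fall of Ddx4. The camera call of this list ended without wildtype array 2 and without double-knockout arrays 1 and 2.

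The piRNA pathway and transposon control list had 7 of 20 tested members lower, 0 higher and 13 that did not pass (median -0.54; camera adjusted p = 8.18e-05; adjusted p = 0.538 with an estimated correlation). Adjusted over the list alone, 8 fell, and 1 of 18 did over all genes without wildtype array 2. Mov10l1, an RNA helicase (-1.78), Piwil2, a PIWI protein (-1.71), and Tdrd1, a Tudor protein (-1.41), fell, with adjusted p = 0.0517 for Piwil2 and 0.0560 for Tdrd1 without wildtype array 2. In the list of 12 tested primordial germ cell and pluripotency genes, 4 fell, 2 rose and 6 did not pass, both over all genes and adjusted over the list alone (median -0.18; camera adjusted p = 0.229). The counts were 2 that fell and 1 that rose without either wildtype array. Sall4, a zinc finger factor of stem and germ cells, fell (-2.34, or -1.55 with no background correction) and was detected on 3 double-knockout arrays. Dppa4, a chromatin factor of pluripotent cells, rose by 1.88, and Nanos2, which acts in male germ cells, rose by 1.72 (1.01 with no background correction) but had adjusted p = 0.116 without wildtype array 2 and 0.0740 without 3.

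Among 22 pregranulosa and granulosa markers, 0 fell, 3 rose and 19 did not pass, with 4 rising when adjusted over the list alone (median 0.28; camera adjusted p = 0.0387; adjusted p = 0.539 with an estimated correlation). The median was -0.03 without wildtype array 2, with 11 of 22 members positive and 0 that rose, and without wildtype array 3 the median was 0.57 and 1 rose. Hsd17b1, an enzyme of estradiol synthesis, rose by 1.08, Runx1 by 0.67 and Amhr2, the receptor of anti-Müllerian hormone, by 0.63. Without wildtype array 2 their adjusted p-values were 0.0830, 0.160 and 0.349. Runx1 also lost its call without wildtype array 3 (0.114) and double-knockout array 1 (0.0592), and Amhr2 without any of the 6 arrays; another Runx1 probe gave -0.47. Among 15 Sertoli and testis-determining markers, 5 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.41; camera adjusted p = 0.0206; adjusted p = 0.538 with an estimated correlation). The number that rose was 0 without either wildtype array and 2 without double-knockout array 1. Cst9, a cystatin, rose by 1.15, Sox10 by 0.85 and Aard by 0.79, while Tesc, a calcium-binding protein, fell (-2.06, or -1.42 with no background correction). Sox9, the testis-determining transcription factor, rose by 0.63 and Gdnf, a growth factor for germ stem cells, by 0.77, both named after their values were seen. Cst9, Sox10 and Aard lost their calls without wildtype array 3 (adjusted p = 0.0760, 0.0685 and 0.105) and without wildtype array 2 (0.0544, 0.135 and 0.154), and Aard also without double-knockout array 1 (0.0564). Sox9 lost its call without any of the 6 arrays (up to 0.311), and Gdnf without either wildtype array or double-knockout array 1 (up to 0.154).

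Of 13 ovarian surface epithelium markers, 1 fell (Gpm6a), 0 rose and 12 did not pass, also adjusted over the list alone (median -0.35; camera adjusted p = 0.0303; adjusted p = 0.538 with an estimated correlation). Gpm6a was at least 1.29-fold lower after background correction, a bound that does not hold without it or with an offset of 50. Of 10 oviduct and mesonephric epithelium markers, 1 fell (Cdh16, -1.06) and 9 did not pass, with 3 falling when adjusted over the list alone (median -0.37; camera adjusted p = 0.0206; adjusted p = 0.538 with an estimated correlation). Among 7 erythroid markers, Alas2, the erythroid enzyme of heme synthesis, rose by 1.34 and 6 did not pass, with 2 rising when adjusted over the list alone (median 1.34, or 1.01 with undetected members at their bound; camera adjusted p = 0.0387; adjusted p = 0.538 with an estimated correlation). Hba-a1, an alpha globin, gave 0.09 and Slc4a1, the red cell anion exchanger, 3.71 ± 1.03 (SE, adjusted p = 0.0625), both named after their values were seen. Alas2 lost its call without either wildtype array or double-knockout array 1 or 3 (adjusted p up to 0.223), Cdh16 without either wildtype array or double-knockout array 3 (up to 0.195), and Gpm6a without double-knockout array 1, 2 or 3 (up to 0.0512). The Gpm6a call also ended with no background correction (-0.35, adjusted p = 0.0648), an offset of 50 (-0.29, 0.0857), 75th percentile scaling (-0.51, 0.0973), the authors' values (-0.36, 0.0575) and either replicate block (up to 0.104). With either wildtype array left out, Gpm6a did not pass the detection filter and was not tested. Slc4a1 passed without double-knockout array 2 (4.64, adjusted p = 0.00326).

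Of 14 endothelial markers, Sox18, a transcription factor of vessel formation, rose by 1.34 and 13 did not pass, with 2 rising when adjusted over the list alone (median 0.26; camera adjusted p = 0.0628). Of 13 theca, steroidogenic and stromal markers, Cyp17a1, an enzyme of androgen synthesis, rose by 0.83 and 12 did not pass, also adjusted over the list alone (median -0.09, mean 0.04; camera pointed up with adjusted p = 0.940). Cyp17a1 had adjusted p = 0.0893 without wildtype array 2 and 0.114 without 3. Among 15 macrophage and leukocyte markers 0 passed, and 0 did adjusted over the list alone (median 0.06, while camera pointed down with adjusted p = 0.836), with Laptm5 at 0.77 and Lyz1 at 0.49. Among 9 smooth muscle and pericyte markers 0 passed, also adjusted over the list alone (median 0.11, mean -0.11; camera pointed down with adjusted p = 0.639), with Acta2 at -0.31 and Smtn at 0.11. The other Acta2 probes gave -0.73, -0.74 and -0.54 and the other Smtn probes -0.42 and 0.26, and none passed. Only 2 adipocyte markers were tested, Lpl at 0.28 and Pparg at 0.76, and neither passed, though 1 rose adjusted over the list alone.

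In the proliferation list, 1 of 13 tested genes fell (Tyms, thymidylate synthase, -0.65), 0 rose and 12 did not pass, with 4 falling when adjusted over the list alone (median -0.44; camera adjusted p = 0.00153; adjusted p = 0.538 with an estimated correlation). For primordial follicle activation, 3 of 15 genes fell (Gdf9, Kit and Foxo3) and 12 did not pass, with 4 falling when adjusted over the list alone (median 0.10, mean -0.40; camera pointed down with adjusted p = 0.229). Among 17 p53 targets and apoptosis genes, Trp63, a p53 relative of oocytes, fell (-1.23), Bbc3, a pro-apoptotic gene, rose (0.84) and 15 did not pass, with 3 falling and 3 rising when adjusted over the list alone (median 0.05; camera adjusted p = 0.941). Among 10 immediate early and heat shock genes, Zfp36, an mRNA decay factor, rose by 1.44, the heat shock gene Hspa1a rose by 0.61 and 8 did not pass, with 1 falling and 4 rising when adjusted over the list alone (median 0.42; camera adjusted p = 0.157). Tyms, Trp63, Bbc3, Zfp36 and Hspa1a lost their calls without wildtype array 2 (adjusted p = 0.222, 0.259, 0.187, 0.191 and 0.226). Each but Bbc3 also did without wildtype array 3, each but Zfp36 without double-knockout array 1, Trp63 without arrays 2 and 3, and Hspa1a without arrays 3 and 5. The other Bbc3 probes gave 0.08 and 0.23.

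None of the 9 Notch pathway genes passed (Hes1 0.47, Hey1 0.02; median 0.22; camera adjusted p = 0.154), and neither did any of 16 extracellular matrix genes (Sparc -0.03, Col6a1 -0.32; median -0.16; camera adjusted p = 0.261). The same held for 12 reference genes (Eef1a1 0.04, Ppia -0.11; median 0.03, mean 0.00; camera pointed down with adjusted p = 0.982). In these lists 0 genes passed when adjusted over the list alone. Of the sex-linked genes, Xist gave -0.44 and the Y-linked Uty -0.24 (detected on 2 of 4 double-knockout arrays), and neither passed over all genes or adjusted over the list alone. In all, camera called 11 of 23 testable lists, 8 lower and 3 higher, and with an estimated correlation it called 0.

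**Figure D2:**
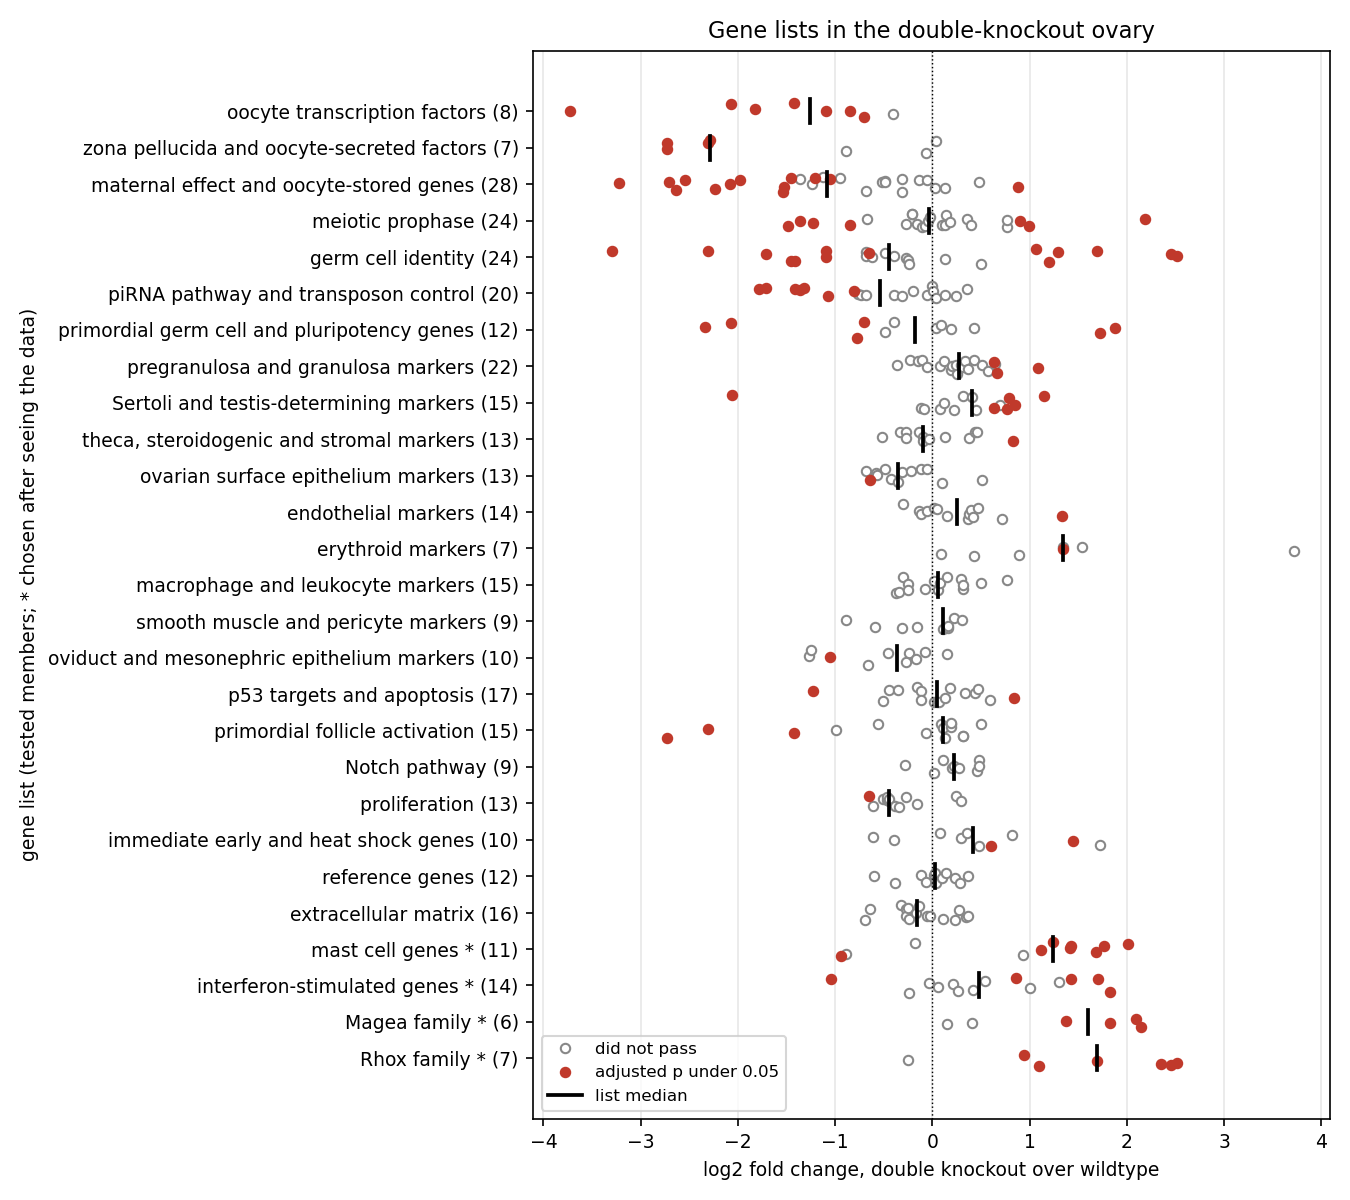
Log2 fold change, double knockout over wildtype, of each tested member of 23 gene lists fixed before the data were examined and 4 chosen after (starred), with filled points for genes past the threshold and black bars at list medians. The oocyte transcription factors (median -1.26), zona and secreted factors (-2.29) and maternal genes (-1.09) lie to the left, while the meiotic prophase list (-0.03) spreads to both sides.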

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

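No explanation was tested for the values in this part. The 4 double-knockout arrays were checked on 153 values: named genes, list means and measures of whole arrays such as detected probes. Of these, 7 had 1 array set apart from the other 3 by Dixon's 95% critical value for the gap over the group's range. Chance alone gives 7.65. Array 1 held 3 of them, arrays 2 and 3 held 2 each and array 5 held 0. The check takes each value alone, so a shift shared by several genes can stay under the critical value in each. Array 5 was highest for Zp3 (8.95, others 6.78 to 8.04) and Nlrp14 (9.58, others 7.18 to 8.21). It was not for Gdf9, Btg4 or Mos. With array 5 left out, the maternal list mean was -1.24, against -1.08 with all arrays and -1.11 to -1.02 without another knockout array. The zona and secreted factor mean was -1.79, against -1.57 and -1.63 to -1.39.

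Noct had array 1 at 4.82 on the log2 scale and the others at 4.42 to 4.45 (gap 0.913 of the range). Syt16 had array 3 at 4.72 and the others at 5.09 to 5.14 (0.876). Mos had array 1 at 4.91 and the others at 4.48 to 4.55 (0.840). Tesc had array 3 at 4.96 and the others at 5.49 to 5.58 (0.854). Cst9 had array 2 at 8.41 and the others at 7.90 to 7.99 (0.831). Hes1 had array 2 at 9.22 and the others at 9.61 to 9.67 (0.860). The mean of the primordial follicle activation list was 8.63 on array 1 and 8.54 to 8.55 on the others (0.962). Noct, Syt16, Mos and Tesc fell (-4.21, -4.09, -2.08 and -2.06) and kept their calls without the array set apart.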

How the results depend on the processing

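No alternative reported here was chosen after seeing the data. The slide could not be fitted as a block, because all arrays lie on 1 slide. Leaving out a wildtype array leaves a lone one, which is then assumed to vary like the double-knockout arrays. Of 81 called named genes, 38 kept their call under every alternative in which they were tested, among them Sohlh1, Ccno, Lhx8, Gdf9, Kit, Sis and Rec8. Over 1450 comparisons, 1277 kept the call, 173 lost it and 0 reversed. Without wildtype array 2, 37 of 77 such genes kept it, and without wildtype array 3, 47 of 77. Of 26 called genes named after their values were seen, 9 kept their call throughout; 403 of 468 comparisons kept it and 65 lost it. Of 664 comparisons of named genes that did not pass, 40 passed. For the lists, 401 of 460 comparisons were on the same side, 47 lost and 12 gained a call, and 0 reversed. With no filter, which tested 19057 genes, 742 passed, 637 of them shared, and the cause was not tested.

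Without single arrays, probes called numbered 224 to 1458, probes called lower in knockout 111 to 693 and probes called higher in knockout 113 to 765; genes called numbered 160 to 946, genes called lower in knockout 71 to 396 and genes called higher in knockout 89 to 552. The lowest gene counts came without wildtype array 2 (160, of which 153 shared), wildtype array 3 (289, 275 shared) and double-knockout array 1 (567, 541 shared). These fits have fewer samples. At an adjusted p under 0.01, 475 probes passed (242 lower, 233 higher), and with a log2 change of at least 1, 663 (347 lower, 316 higher), as both demand more. Apart from no filter (742), other processing of all 6 arrays without a block gave 1031 to 1456 genes, with 0 in the opposite direction. The share of calls that were higher was 57.2%, and 51.2% to 62.0% over all alternatives.

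With a replicate block by title number, probes called numbered 888 (probes called lower in knockout 453, probes called higher in knockout 435) and genes called 591 (genes called lower in knockout 265, genes called higher in knockout 326), and by description number 804 genes. Deviations of arrays with the same title number correlated at -0.10 and -0.03, and by description number at -0.11 and 0.10. With 2 wildtype arrays their deviations mirror each other, so this check settles nothing about pairing, and no label states what the numbers share. Each number had its own term in the block fits. An array without a same-numbered array of the other genotype therefore did not enter the comparison. The block by title compared double-knockout arrays 2 and 3 with wildtype arrays 2 and 3. The block by description compared double-knockout arrays 1 and 2 with the same wildtype arrays. The block by title left granulosa markers at a mean of 0.24 without a call. The block by description ended calls for surface epithelium (-0.078) and oviduct markers (-0.26) and gave one for endothelial markers (0.33). How far these changes come from the fewer arrays compared was not tested.

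The camera call ended with an estimated correlation for each of the 11 called lists, whose means were -1.51 for oocyte transcription factors, -1.57 for zona and secreted factors, -1.08 for maternal genes, -0.24 for germ cell identity, -0.59 for piRNA genes, 0.27 for granulosa, 0.28 for Sertoli, -0.29 for surface epithelium, 1.33 for erythroid and -0.53 for oviduct markers and -0.33 for proliferation. Correlated members widen that test. Under fry, which does not compare a list with other genes, 10 of these calls ended, all but oocyte transcription factors. Primordial follicle activation (-0.40) gained a call under fry. The 3 members of that list that fell are also in the zona and secreted factor list (Gdf9 and Kit) or the oocyte transcription factor list (Foxo3).

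The stricter filter ended calls for germ cell identity (-0.24), granulosa (0.29), Sertoli (0.25), surface epithelium (-0.29) and erythroid markers (1.51 over 5 members), the mean of probes ended that of germ cell identity (-0.22), and no filter ended that of erythroid markers (0.92 over 10 members, while the 7 tested otherwise stayed at 1.33). Each mean covers the members tested under that alternative. Endothelial markers gained a call with no background correction (0.24), offset 50 (0.24), no filter (0.26), the authors' values (0.24) and the mean of probes (0.29). The cause was not tested.

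Without single arrays, some calls ended for lists with means of -0.30 to -0.17 (germ cell identity; without wildtype 2, double knockout 1 or 2), 0.11 to 0.43 (granulosa; the same arrays), 0.23 to 0.33 (Sertoli; wildtype 2), -0.38 to -0.21 (surface epithelium; wildtype 2 or 3, double knockout 3 or 5), 0.97 to 1.65 (erythroid; wildtype 2 or 3, double knockout 1 or 3) and -0.66 to -0.38 (oviduct; wildtype 3). Calls were gained for endothelial markers (0.18 to 0.34; wildtype 3 or double knockout 3), immediate early genes (0.36 to 0.79; wildtype 3 or double knockout 2) and extracellular matrix (-0.23 to 0.01; wildtype 2). The cause was not tested.

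Among genes named in the report and the other observations, no filter ended the calls of Nlrp14, Ap3b2, Zp3, Zp1, Sycp2, Nanos2, Amhr2, Alas2, Cdh16, Trp63, Zfp36, Nlrp4c, Sox9, Cpa3, Gata2, Usp18, Gbp3, Magea6 and Hif1a (adjusted p up to 0.147). The trend and robust variance prior ended those of Nlrp14, Ap3b2, Zp3, Zp1 and Alas2 (up to 0.143), no background correction and an offset of 50 those of Sycp2 and Gpm6a, 75th percentile scaling those of Amhr2 and Gpm6a, cyclic loess that of Amhr2 and the authors' values that of Gpm6a (up to 0.0973). The mean of probes ended those of Runx1 (0.10, adjusted p = 0.650), Amhr2, Bbc3, Sox9 and Gbp3. The block by title number ended those of Mnd1, Runx1, Amhr2, Sox10, Aard, Cyp17a1, Gpm6a, Alas2, Bbc3, Tyms, Hspa1a, Nlrp4c, Sox9, Gdnf, Gata2, Gbp3 and Hif1a (up to 0.158), and by description number those of Sycp2, Amhr2, Gpm6a, Cdh16, Tyms, Hspa1a, Sox9, Gdnf, Gata2 and Gbp3 (up to 0.142). With all arrays kept, Laptm5 gained a call under 4 alternatives, Pparg under 5 and Slc4a1 under 2. The cause was not tested.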

Other observations

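The mast cell, interferon, Rhox and Magea lists were chosen after the values were seen, so their counts are not independent evidence. So were the tests of fewer germ cells, scaling, dilution, the shares of X-linked genes that rose and fell, white cells, blood, adjoining tissue and neighbours of the targeted genes; those of the X-linked median, a linked segment and genes side by side were set before their results were seen.

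Of 11 tested mast cell genes, 7 rose, 1 fell (Gata2, -0.94) and 3 did not pass. Mrgprb2, a receptor of connective tissue mast cells, rose 4.02-fold (2.01 ± 0.18 SE, n = 2 and 4), and the tryptases Tpsb2 and Tpsab1 rose by 1.77 and 1.69. Mcpt4 rose by 1.43, Cma1 by 1.42, Hdc, which makes histamine, by 1.24 and Cpa3 by 1.12. The brightest tryptase, Tpsb2, had log2 levels of 9.08 in wildtype and 10.85 in double-knockout arrays. Without wildtype array 2, and also without wildtype array 3, 4 rose. Mrgprb2, Tpsb2 and Cma1 kept their calls under every alternative, Gata2 in 11 of 18 and Cpa3 in 14. Calls ended without wildtype array 2 for Tpsab1, Hdc, Cpa3 and Gata2 (adjusted p = 0.108, 0.141, 0.0917 and 0.287), without wildtype array 3 for Mcpt4, Hdc, Cpa3 and Gata2 (0.0574, 0.0642, 0.156 and 0.113), without double-knockout array 1 for Cpa3 and Gata2 (0.0564 and 0.0811) and without array 3 for Gata2 (0.0650). Among 14 interferon-stimulated genes, 4 rose (Usp18 1.83, Ifit3 1.70, Isg15 1.43, Gbp3 0.86), Cxcl10 fell (-1.05) and 9 did not pass; 1 rose without wildtype array 2, 2 without wildtype array 3 and 2 of these 14 with no filter. Usp18 and Isg15 lost their calls without either wildtype array (adjusted p up to 0.133 and 0.0891), Cxcl10 without wildtype array 3 (0.0911) and Gbp3 without any array but double-knockout array 2 (up to 0.213).

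On the X chromosome, 6 of 7 tested Rhox homeobox genes rose (Rhox9 2.51, Rhox5 2.35, Rhox13 1.69, Rhox8 1.09, Rhox1 0.94, and Rhox6 at least 4.33-fold after background correction, or 1.51 without it and 1.44 with an offset of 50), and Rhox12, detected on 3 of 4 double-knockout arrays, gave -0.25. Rhox9, Rhox6 and Rhox13 are also in the germ cell identity list. Of 6 Magea genes, 4 rose (Magea5 2.14, Magea2 2.09, Magea8 1.83, Magea6 1.37, detected on 1 of 2 wildtype arrays). The same numbers rose under each other scaling. Without wildtype array 2, 5 Rhox and 2 Magea genes rose, and without wildtype array 3, 5 and 3. Rhox1 and Magea6 lost their calls without either wildtype array (adjusted p up to 0.0881 and 0.205) and Magea8 without wildtype array 2 (0.0586). Some copies in both families may be near identical, and probe sequences were not compared, so probes cannot be relied on to tell every member apart.

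The fall of oocyte genes could reflect fewer germ cells, an effect of processing, or loss of both transcription factors. Fewer germ cells as the whole cause would lower meiotic genes alike, provided the lost cells carried these transcripts. The meiotic median was -0.032 (quartiles -0.23 and 0.37), against -1.13 for 43 pooled oocyte genes. Other germ cell lists had lower medians than the meiotic list: -0.54 for piRNA genes, -0.45 for germ cell identity and -0.18 for primordial germ cell and pluripotency genes. Over 5 other scalings and sources the weakest mean of the pooled genes was -1.01, against -1.24. Fewer oocytes as part of the cause stays open, as do oocytes of another stage. An effect of the genotype within germ cells is a hypothesis, found and tested on the same data.

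The rise of Rhox and Magea genes could come from dilution by lost oocyte RNA, from the X chromosome as a whole, or from the genotype. Dilution would lift markers of somatic cells by as much as both families, a comparison that no shift common to all genes can set. All 13 tested members of the families had a median of 1.69 (quartiles 0.94 and 2.14). That is 1.58 above the median of 117 markers from 10 somatic cell lists (0.11, quartiles -0.24 and 0.42). Both families were chosen after their values were seen, so this gap is not independent evidence. Rhox9, Rhox6 and Rhox13 are also in the germ cell identity list, and which cells carry these transcripts is not known here. The 401 X-linked genes outside the families had a median of 0.024 (quartiles -0.21 and 0.24). Of these, 6.98% rose against 4.64% of 11739 others (Fisher's exact test, two-sided p = 0.0404, 0.0809 after adjustment over this test and that of falls), and 3.99% fell against 3.58% (p = 0.681, also 0.681 after adjustment). Copies that share probes stay open.

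The rise of mast cell genes could come from a rise of all white cells alike, from more blood in the sample, from 1 chromosome segment, from adjoining tissue, or from more mast cells in the ovary. The macrophage and leukocyte list, fixed before the data were examined, had a median of 0.060 (quartiles -0.25 and 0.31). Of its 15 members 0 passed, 9 were above 0 and 6 below, and Laptm5 gave 0.77 (adjusted p = 0.0673). A small rise of these markers is not excluded. All 11 mast cell genes had a median of 1.24, but that list was chosen after its values were seen. The gap between the lists is therefore not independent evidence. More blood cannot be told apart: the 7 erythroid markers were all higher, with a median of 1.34 (1.01 with undetected members at their bound; camera adjusted p = 0.0387, but 0.538 with an estimated correlation), 1 of them passed, and the bright Hba-a1 gave 0.09. The erythroid median was 0.82 without double-knockout array 1 and 0.79 without array 3, with 0 passing. The 7 risen mast cell genes lie on 5 chromosomes. Adjoining connective tissue cannot be told apart: extracellular matrix had a median of -0.16 and smooth muscle 0.11, and a small piece of tissue would move these bright lists little. The number of mast cells was not measured.

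Among the 100 tested genes nearest Sohlh2, 14 were called, Noct (-4.21) and Sis (3.97) among them, against 8.39 expected (exact one-sided p = 0.0391, 0.0782 after adjustment over both targeted genes), and 7 near Sohlh1 (exact one-sided p = 0.744). A strain segment carried with the targeted alleles cannot be told apart from chance or from an effect of genotype there.

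Risen genes outside the Rhox and Magea families formed 34 adjacent pairs, against a mean of 26.9 in 10000 permutations over 12140 placed genes (one-sided permutation p = 0.095), which leaves open whether they cluster. Fallen genes formed 38, against 15.6 (one-sided permutation p = 1e-04, the smallest these permutations can give). Leaving out 8 pairs of like-named genes left 30, against 14.9 (one-sided permutation p = 2e-04), so tandem copies of gene families are not the whole cause. Among them were Slc7a11 (-1.63) beside Noct, Add2 (-2.33) beside Figla and Hif1a (-1.06) beside Syt16. Slc7a11, Add2 and Hif1a were named after their values were seen. Slc7a11 and Noct are both among the 100 tested genes nearest Sohlh2, and those genes were not left out of the permutations. Add2 kept its call under every alternative. Slc7a11 lost its call without wildtype array 2 (adjusted p = 0.0654), Figla without either wildtype array (up to 0.0816) and Hif1a without wildtype arrays 2 and 3 (0.270 and 0.0844), double-knockout arrays 1 and 2 (0.0595 and 0.0637), with no filter (0.101) and with the block by title number (0.0861).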
